A study of Mus musculus with 12 samples.

How the data were processed

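RNA was sequenced from CD8+ T cells sorted out of Panc02 tumours, which grow from a mouse pancreatic tumour cell line, in wild type C57BL/6J mice. Per the labels, the sort took viable (DAPI-negative) CD45.2+ CD8+ cells that were negative or positive for asGM1 (asialo-GM1, a glycosphingolipid of the cell surface), and the tumours had received an isotype control or an anti-PD-1 antibody. No CD3 or T cell receptor gate was named. Crossing population and treatment gave 4 groups of 3 libraries, 12 libraries in all. Whether replicates of a group came from separate mice was not stated, so p-values measure the spread between these libraries, which may be partly technical.

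RNA was extracted with TRIzol, and a SMARTer ultra-low-input kit and a TruSeq mRNA kit were named for the libraries, per the labels' protocols. HISAT2, StringTie and the mouse genome build mm39 were named, per the submitters' processing notes. Their versions, their settings and the gene annotation were not given in the sources used here. The authors deposited 1 table of whole-number counts per gene, with gene IDs and symbols and with replicates kept apart. Whether these counts were tallied read by read or derived from StringTie's coverage estimates was not stated, and the values do not settle it. Use of strand and of reads with several matches was not stated either. Values of near-identical paralogs (Gzmd and Gzme, Hspa1a and Hspa1b, the Klra family, duplicated Trav segments) and of overlapping or antisense genes are therefore uncertain.

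The table held 56941 genes, and 61.4% of its values were 0. Totals ran from 58.1 to 73.2 M counts per library, so that 3 counts, the largest true mean that an observed count of 0 allows at 95% confidence, corresponded to 0.0410 to 0.0516 CPM (counts scaled to a library total of 1 M, where M stands for mega). Such limits cover counting error only, since PCR copies are not independent molecules. The 10 most abundant genes took 4.98 to 6.28% of counts and mitochondrially encoded genes 0.309 to 0.782%. The 310 genes with an ID and no symbol held 0.0387 to 0.0547% of counts and stayed in the totals and tests, and 147 symbols were shared by more than 1 ID. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 43.5 to 121), so no library was a copy of another. The reference at hand was build GRCm38, which differs from mm39; it gave names for 51948 of the gene IDs as a check and no coordinates are printed.

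Counts were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in 1 fit of all 12 libraries with a mean per group, after edgeR's default expression filter by group and TMM scaling (factors 0.970 to 1.04). The filter left 18657 genes. The fit had 8 residual degrees of freedom, a median of 3.79 prior degrees of freedom and a biological coefficient of variation of 0.336. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were asGM1-positive minus asGM1-negative under each treatment and averaged, anti-PD-1 minus isotype in each population and averaged, and the interaction. Every adjusted p of a gene is from edgeR unless another tool is named, and standard errors are the log2 fold change divided by the root of F. CPM values are scaled by the TMM factors and given as mean ± SD over the 3 libraries of a group.

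For groups of genes, 31 lists covering T cell states, metabolism and markers of other cells were fixed. All 627 listed names were found, 5 of them under an older symbol, and 30 lists had at least 5 measured members. Each was tested with limma's camera on voom log2 CPM with an inter-gene correlation of 0.01, two-sided and adjusted over the lists of a contrast. Camera compares a list with the other genes, while the number of members past the threshold is a separate count, given over all genes tested and adjusted over the list alone. With an estimated correlation in place of 0.01, 2 of 101 list calls over all contrasts held, both for CD4 and regulatory T cell markers. The adjusted p obtained that way is given in the Results beside each passing camera test that is printed there. Not every list that passed is printed. A list of plasmacytoid dendritic cell genes and a list of heat shock genes were added after the data were seen and have no camera test.

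The design, the 31 lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per contrast, the 8 largest rises and 8 largest falls (4 and 4 for averaged contrasts and the interaction) among genes past the threshold with an average log2 CPM of at least 3 and groups that did not overlap, leaving out predicted genes and immunoglobulin and T cell receptor variable segments. It also took up to 4 members per list with the smallest p, and 28 genes that were named whatever their result. With 3 libraries against 3, chance alone puts 10% of genes in non-overlapping order.

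Replicate numbers were checked for pairing by correlating deviations from group means. Libraries of the same treatment and number correlated in all 6 pairs (r 0.209 to 0.705 across 9257 genes; 0.874 to 0.915 across 133 T cell receptor V segments with at least 100 counts), while those of the same treatment and another number reached 0.264 across genes and -0.342 across V segments. By V segments all 12 libraries matched their own number best, and across genes 10 of 12 did. Equal numbers under different treatments did not pair (r -0.427 to 0.233). By the V segments the numbers therefore pair the populations within a treatment, as sorting both from the same tumour would, although the labels do not say so. Population contrasts and the interaction were refitted with that pair as a block.

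On counts simulated for the population contrast under isotype (18090 genes), edgeR recovered 31 of 100 genes changed 2-fold and 79 of 100 changed 4-fold, and 5 of 115 calls were false. The block within treatment recovered 51 and 81, with 6 of 138 calls false. DESeq2 recovered 57 and 92 on 18657 genes, with 29 of 178 calls false. For the treatment contrast in asGM1-negative cells (18112 genes) edgeR recovered 22 and 80, with 3 of 105 false. For the interaction (18112 genes) it recovered 1 and 53, with 3 of 57 false, and with the block 18 and 63, with 1 of 82 false. Changed genes were drawn from those with a mean of at least 1 CPM. The simulated pair effect had a preset size that was not estimated from these libraries, so rates with and without the block may differ in the real data. Alternatives were RLE size factors, library size alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma voom with quality weights, only the 2 groups compared, replicate blocks, other list tests and each library left out in turn.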

Results

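Intratumoral CD8+ T cells were profiled by bulk RNA sequencing to ask what sets asGM1-positive cells apart from asGM1-negative cells and how both respond to PD-1 inhibition. Each group had 3 libraries, with mean totals of 64.2 ± 7.92 M counts for isotype asGM1-negative cells and 66.1 ± 7.43 M for isotype asGM1-positive cells (SD, n = 3 each). Under anti-PD-1 the totals were 61.6 ± 3.64 M for asGM1-negative and 65.9 ± 5.98 M for asGM1-positive cells. The first principal component of log2 CPM held 21.6% of the variance and separated the treatments. The second held 18.4% and separated the populations.

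**Figure D1:**
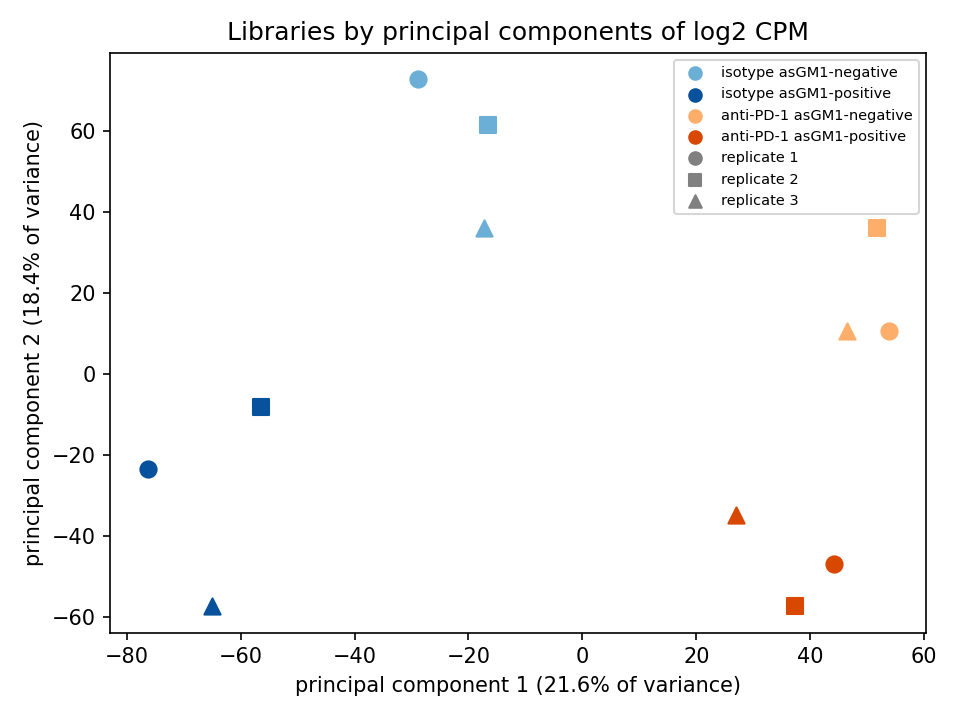
Principal components 1 (x, 21.6% of variance) and 2 (y, 18.4%) of the log2 CPM of the 12 libraries, 1 point per library. Isotype libraries lie between -76.4 and -16.6 on the first component and anti-PD-1 libraries between 27.1 and 53.8, while asGM1-negative libraries lie between 10.7 and 72.8 on the second and asGM1-positive libraries between -57.3 and -8.02.

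Under isotype treatment, asGM1-positive cells carried less RNA of genes that mark naive and recirculating T cells than asGM1-negative cells did. S1pr1, the sphingosine-1-phosphate receptor used for exit from tissue, fell from 17.8 ± 6.87 to 1.72 ± 0.368 CPM (log2 fold change -3.37 ± 0.33 SE, edgeR adjusted p = 0.00112), and Ccr7, a chemokine receptor for lymph node entry, from 82.0 ± 19.8 to 15.4 ± 7.52 CPM (-2.42 ± 0.31, adjusted p = 0.00384). Tcf7, which encodes the transcription factor TCF1 of naive and stem-like T cells, fell by 2.74 ± 0.48 on the log2 scale and Il7r, the interleukin-7 receptor, by 0.77 ± 0.13. The call of Tcf7 ended without isotype asGM1-negative replicate 1 or 3 or isotype asGM1-positive replicate 1 (edgeR adjusted p = 0.0610, 0.0680 and 0.0758). That of Il7r ended without isotype asGM1-negative replicate 1 (0.0577). Of 24 measured naive and stem-like memory genes, 13 fell, 0 rose and 11 did not pass (18 fell adjusted over the list alone), with a median log2 change of -0.91 (camera adjusted p = 1.85e-20; adjusted p = 0.0546 with an estimated correlation, and 0.0153 with the pair as a block as well).

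The largest falls were in genes better known from other lineages. Siglech, a surface lectin of plasmacytoid dendritic cells, went from 58.6 ± 12.6 to 0.0787 ± 0.136 CPM (-9.39 ± 0.96, edgeR adjusted p = 0.00112). Ly6d, found on lymphoid progenitors and plasmacytoid dendritic cells, went from 28.7 ± 12.7 to 0.187 ± 0.191 CPM (-7.21 ± 0.89, adjusted p = 0.00384), and the gut homing receptor Ccr9 from 22.3 ± 4.43 to 0.273 ± 0.473 CPM (-6.28 ± 1.10, adjusted p = 0.0185). Ccr9 did not pass without isotype asGM1-negative replicate 1 or 3 (0.0643 and 0.0616), and Siglech and Ly6d did not pass under limma voom (adjusted p = 0.0517 and 0.145). Of 16 plasmacytoid dendritic cell genes, listed after the data were seen, 13 fell and 3 did not pass (15 fell adjusted over the list alone). Foxp3, the transcription factor of regulatory T cells, fell from 29.0 ± 12.7 to 3.22 ± 1.22 CPM (-3.17 ± 0.46, adjusted p = 0.00691). Of 10 CD4 and regulatory T cell markers, 2 fell and 8 did not pass (5 fell adjusted over the list alone; camera adjusted p = 4.67e-06, and adjusted p = 0.0464 with an estimated correlation). These genes were thus lower in the same libraries as the naive and stem-like genes. The CD4 and regulatory T cell list is not specific to other cells. Its members Tnfrsf4 and Il2ra are also in the T cell receptor activation list, and Ctla4 and Ikzf2 in the exhaustion list. Tnfrsf4 was at 157, 110 and 113 CPM in isotype asGM1-positive libraries, where Cd4 was at 1.20, 2.62 and 5.41 CPM. Cd8a, the sorted marker, was at 2111 ± 60.5 and 2403 ± 188 CPM and did not pass (0.19 ± 0.09, adjusted p = 0.424).

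Macrophage genes were higher in the asGM1-positive libraries. Apoe, which encodes a lipoprotein made by macrophages, rose to 80.4 ± 15.3 CPM (2.42 ± 0.24, edgeR adjusted p = 0.00112), and the complement component genes C1qb, C1qc and C1qa rose by log2 fold changes of 2.25 ± 0.29, 2.20 ± 0.26 and 2.05 ± 0.25. Tgm2, a transglutaminase, rose by 2.32 ± 0.33, and Lyz2, the lysozyme of myeloid cells, by 2.13 ± 0.35. Lyz2 did not pass without isotype asGM1-negative replicate 1, 2 or 3 (edgeR adjusted p = 0.0610, 0.0584 and 0.0616). Of 18 macrophage and monocyte markers, 9 rose and 9 did not pass (adjusted over the list alone, 11 rose and 1 fell; camera adjusted p = 6.11e-13; adjusted p = 0.143 with an estimated correlation). In the same libraries Gzmb, the protease granzyme B of cytotoxic cells, rose from 4597 ± 625 to 8151 ± 1450 CPM (0.83 ± 0.15, adjusted p = 0.0189). Gzmb was lost without isotype asGM1-negative replicate 2 or 3 (0.0584 and 0.0735), without isotype asGM1-positive replicate 1 or 2 (0.0644 and 0.0533) and without both libraries of anti-PD-1 replicate 2 (0.0553). It was the only gene to rise of 18 cytotoxic granule genes (2 rose adjusted over the list alone), and 17 did not pass. With the pair as a block the cytotoxic granule list was higher (median 0.17, camera adjusted p = 0.00775), and with the block and an estimated correlation it did not pass (0.375). The effector cytokine and chemokine list went the other way: of 18 genes, 1 fell and 17 did not pass (6 fell adjusted over the list alone), with a median log2 change of -0.31 (camera adjusted p = 1.84e-05; adjusted p = 0.256 with an estimated correlation, and 0.0469 with the pair as a block as well). The gene that fell was Il18rap, a subunit of the interleukin-18 receptor (-0.48 ± 0.09, edgeR adjusted p = 0.0264). It was lost without isotype asGM1-negative replicate 1, 2 or 3 (0.0579, 0.0679 and 0.0832), isotype asGM1-positive replicate 2 or 3 (0.0837 and 0.0714) or anti-PD-1 asGM1-negative replicate 3 (0.0515). Entpd1, the ectonucleotidase CD39 of chronically stimulated T cells, rose by 0.68 ± 0.09 on the log2 scale (adjusted p = 0.00409) and the receptor gene Cd244a by 0.89 ± 0.13. Markers of NK cells, which also make granzyme B, were higher as a list in the same libraries. Of 12, 0 passed (2 rose adjusted over the list alone), with a median log2 change of 0.51 (camera adjusted p = 0.0443; adjusted p = 0.480 with an estimated correlation). That list call ended without isotype asGM1-negative replicate 2 or 3 (0.0783 and 0.185) or isotype asGM1-positive replicate 1 or 2 (0.0624 and 0.0590). With the pair as a block it was kept (0.00152), and with the block and an estimated correlation it was not (0.249). Ncr1, the NK cell receptor NKp46, was at 0.115 ± 0.111 and 0.673 ± 1.02 CPM and did not pass (edgeR adjusted p = 0.540). Fcer1g, named after its values were seen, was at 89.3 ± 30.4 and 255 ± 44.5 CPM and did not pass (edgeR adjusted p = 0.0760). Fcer1g and Fcgr3 belong to the NK cell list and are also expressed by macrophages, whose markers were higher in these libraries. The NK cell list by itself therefore does not separate NK cells from macrophages.

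Under isotype, B4galnt1 and B3galt4, which make asGM1 itself, did not pass between the populations. B4galnt1, the transferase that builds GM2 and its asialo form, was at 1116 ± 213 CPM in asGM1-negative and 1005 ± 131 CPM in asGM1-positive cells (-0.15 ± 0.13, edgeR adjusted p = 0.721), and B3galt4, which adds the terminal galactose, was at 14.2 ± 1.12 and 15.1 ± 1.95 CPM (0.09 ± 0.15, adjusted p = 0.894). Of 30 glycosphingolipid metabolism genes, 3 fell and 27 did not pass (adjusted over the list alone, 3 fell and 1 rose; camera adjusted p = 0.452). All 3 that fell were sialyltransferases, St3gal1 (-0.85 ± 0.15), St3gal2 (-1.31 ± 0.24) and St6galnac3 (-1.26 ± 0.24). The list's sialyltransferases did not all go that way. St3gal5 did not pass, at 3.12, 2.54 and 3.24 CPM in asGM1-negative and 4.82, 3.24 and 6.02 CPM in asGM1-positive libraries. Sialyltransferases were not tested as a class. St3gal1 was lost without isotype asGM1-negative replicate 1, 2 or 3 or asGM1-positive replicate 1 (edgeR adjusted p = 0.0762, 0.0510, 0.0616 and 0.0533). St3gal2 was lost without asGM1-negative replicate 1 or 3 or asGM1-positive replicate 2 or 3 of the isotype groups (0.0643, 0.0747, 0.0533 and 0.0756) and without both libraries of anti-PD-1 replicate 2 (0.0560). St6galnac3 was lost without asGM1-negative replicate 1, 2 or 3 or asGM1-positive replicate 2 or 3 of the isotype groups (0.0747, 0.0840, 0.0553, 0.0855 and 0.0857) and under limma voom (0.114). Pdcd1, which encodes PD-1, did not pass (0.32 ± 0.10, adjusted p = 0.207) without the pair as a block and passed with it (0.33, adjusted p = 0.0380). Other genes that passed with the block and not without it were Cd4 (-2.06, adjusted p = 0.0136), Cx3cr1 (-1.05, adjusted p = 0.0136), Gzma (0.76, adjusted p = 0.0324) and Klrg1 (1.03, adjusted p = 0.00607).

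Between the populations under isotype, 243 genes passed, 68 higher and 175 lower in asGM1-positive cells, and 43 and 138 of them changed at least 2-fold. With the pair as a block, edgeR called 755 genes (359 higher, 396 lower), and with only the 6 libraries compared it called 80. In that smaller fit Ccr9, Tgm2, Gzmb, Cd244a, Il7r, Il18rap, St3gal1, St3gal2 and St6galnac3 no longer passed (adjusted p from 0.0521 to 0.131). DESeq2 called 798. The count moved by over 1.5 times without isotype asGM1-negative replicate 1 (86), replicate 2 (122) or replicate 3 (123), without isotype asGM1-positive replicate 1 (150) and without anti-PD-1 asGM1-negative replicate 3 (159).

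**Figure D2:**
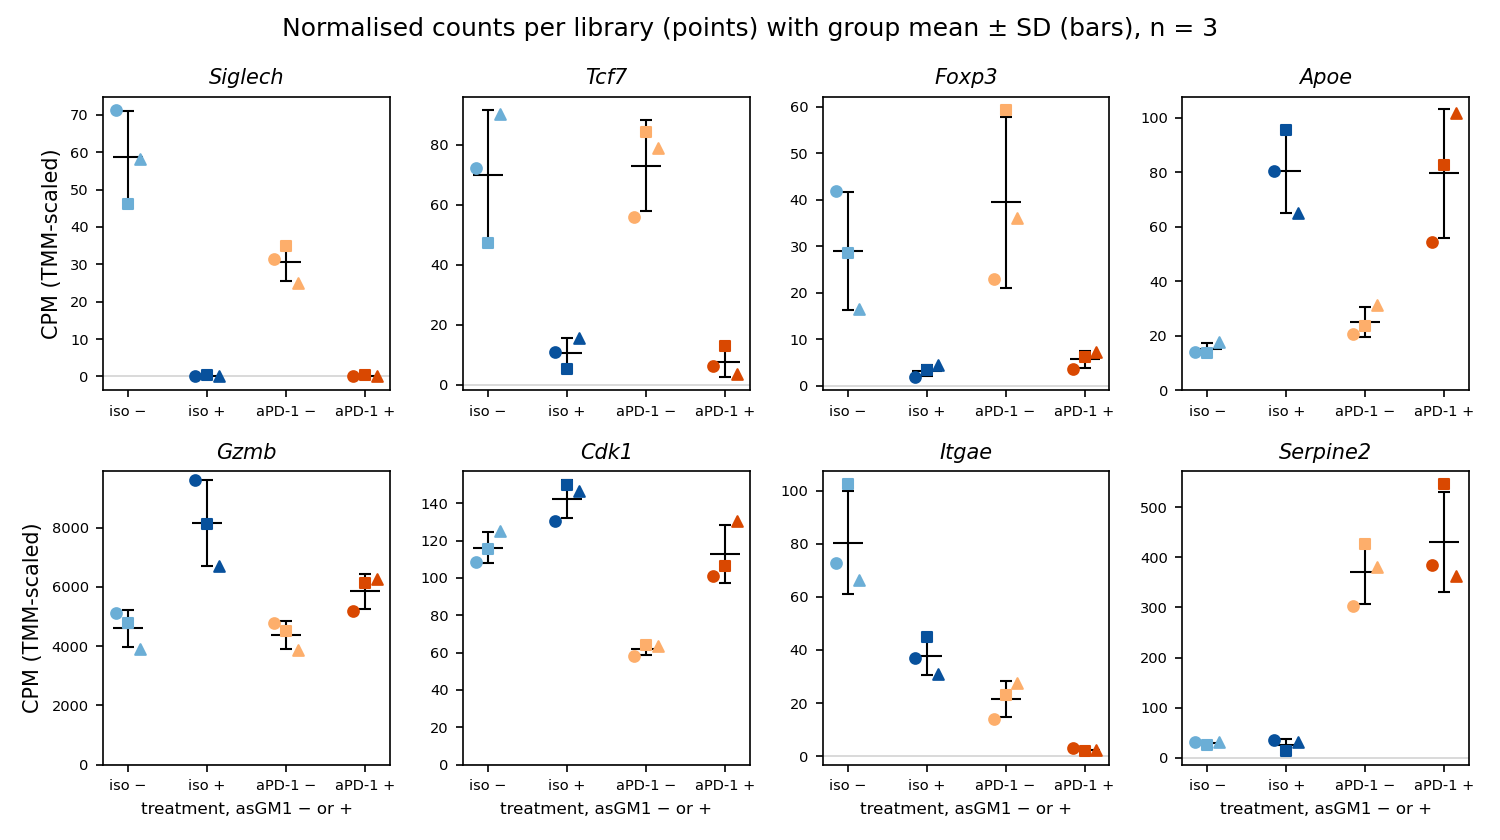
CPM of 8 genes in each library (y, points) by treatment and population (x), with the mean and SD of each group of 3 as bars. Siglech and Tcf7 are lower in asGM1-positive cells under both treatments, and Serpine2 rises from group means of 29.8 and 26.7 CPM under isotype to 370 and 431 CPM under anti-PD-1.

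Under anti-PD-1, asGM1-positive cells carried more cell cycle RNA than asGM1-negative cells. Cdk1, the kinase that drives entry into mitosis, was at 62.0 ± 3.27 CPM in asGM1-negative and 113 ± 15.6 CPM in asGM1-positive cells (0.86 ± 0.11, edgeR adjusted p = 0.00482). Birc5 and Aurkb, components of the chromosomal passenger complex, rose by 0.84 ± 0.11 and 0.94 ± 0.13. Of 33 mitosis genes, 21 rose and 12 did not pass (33 rose adjusted over the list alone), with a median log2 change of 0.84 (camera adjusted p = 2.69e-43; adjusted p = 0.0652 with an estimated correlation, and 0.0359 with the pair as a block as well). Of 30 DNA replication genes, 11 rose and 19 did not pass (30 rose adjusted over the list alone; camera adjusted p = 2.77e-34; adjusted p = 0.0652 with an estimated correlation, and 0.0440 with the block as well), among them Cdc45, a helicase component (0.79 ± 0.12). Without anti-PD-1 asGM1-negative replicate 2, Cdc45 did not pass (edgeR adjusted p = 0.0516). Mki67, a proliferation marker, was at 147 ± 32.2 and 221 ± 63.6 CPM and did not pass (0.59 ± 0.24, adjusted p = 0.356).

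The falls again included Ly6d (6.97 ± 3.87 to 0.0288 ± 0.0498 CPM; -7.75 ± 1.03, edgeR adjusted p = 0.00594) and Siglech (30.5 ± 4.97 to 0.187 ± 0.264 CPM; -7.44 ± 0.87, adjusted p = 0.00382), with Ccr9 (-5.13 ± 1.04) and Tcf7 (73.1 ± 15.1 to 7.52 ± 4.85 CPM; -3.28 ± 0.49, adjusted p = 0.00913). Itgae, the CD103 integrin that binds E-cadherin on epithelium, fell from 21.5 ± 6.88 to 2.40 ± 0.588 CPM (-3.16 ± 0.28, adjusted p = 0.00205). Of 24 naive and stem-like memory genes, 5 fell and 19 did not pass (10 fell adjusted over the list alone; camera adjusted p = 7.28e-10; adjusted p = 0.149 with an estimated correlation). Among 16 plasmacytoid dendritic cell genes, listed after the data were seen, 11 fell and 5 did not pass (13 fell adjusted over the list alone), and among 10 CD4 and regulatory T cell markers 2 fell and 8 did not pass (4 fell adjusted over the list alone; camera adjusted p = 6.96e-05; adjusted p = 0.0652 with an estimated correlation, and 0.0440 with the block as well). Foxp3 fell by 2.81 ± 0.45 on the log2 scale. Without anti-PD-1 asGM1-negative replicate 2, Foxp3 did not pass (edgeR adjusted p = 0.0501), nor did Ly6d under limma voom (0.174). Ccr9 was lost without anti-PD-1 asGM1-negative replicate 1, 2 or 3 (0.0808, 0.124 and 0.0977), anti-PD-1 asGM1-positive replicate 1, 2 or 3 (0.109, 0.0683 and 0.163) or isotype asGM1-negative replicate 1, 2 or 3 (0.0631, 0.0637 and 0.0623), and with no filter (0.0657). Of 15 tissue residency genes, Itgae and Ccr9 fell and 13 did not pass (2 fell adjusted over the list alone; camera adjusted p = 1.15e-05; adjusted p = 0.179 with an estimated correlation). Ccr9 was counted in the plasmacytoid dendritic cell list as well. With the pair as a block, interferon response genes were lower (median -0.31, camera adjusted p = 6.44e-18; adjusted p = 0.0359 with an estimated correlation as well).

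Macrophage genes were again higher in the asGM1-positive libraries, where the cell cycle genes were also higher. C1qc rose from 3.58 ± 0.864 CPM (1.97 ± 0.26, edgeR adjusted p = 0.00571), C1qb by 1.91 ± 0.28, C1qa by 1.71 ± 0.25 and Apoe by 1.67 ± 0.23. C1qb did not pass without anti-PD-1 asGM1-negative replicate 2 (0.0517). Of 18 macrophage and monocyte markers, 7 rose and 11 did not pass (11 rose adjusted over the list alone; camera adjusted p = 2.57e-11; adjusted p = 0.149 with an estimated correlation). Gzmk, a granzyme of memory-like CD8+ T cells, rose from 69.8 ± 18.8 to 161 ± 35.7 CPM (1.21 ± 0.24, adjusted p = 0.0312). It was lost without asGM1-negative replicate 1 or 2 or asGM1-positive replicate 2 or 3 of the anti-PD-1 groups (0.120, 0.160, 0.106 and 0.118) and with the number shared by all groups as a block (0.0508). Gzmb, Pdcd1, Cd8a and B4galnt1 did not pass (adjusted p = 0.254, 0.998, 0.811 and 0.898). Of 30 glycosphingolipid metabolism genes, 1 fell and 29 did not pass (1 fell adjusted over the list alone), and the list was lower (median -0.06, camera adjusted p = 0.0211; adjusted p = 0.416 with an estimated correlation). That list call ended without anti-PD-1 asGM1-positive replicate 1 or 3 (0.159 and 0.200). It was kept with the pair as a block (0.0424), and with the block and an estimated correlation it was not (0.480). The gene that fell was St3gal2, from 14.3 ± 0.599 to 5.66 ± 0.343 CPM (-1.34 ± 0.24, edgeR adjusted p = 0.0194). St3gal2 was lost without asGM1-negative replicate 1, 2 or 3 (0.0589, 0.0781 and 0.0622) or asGM1-positive replicate 1, 2 or 3 (0.0642, 0.0611 and 0.0913) of the anti-PD-1 groups, and without both libraries of replicate 2 (0.189). With the pair as a block, Prf1, the pore-forming protein perforin (0.51, adjusted p = 0.00650), and Tox (0.55, adjusted p = 0.0217) passed higher, and Il7r (-0.52, adjusted p = 0.0145), Slamf6 (-0.81, adjusted p = 0.0407) and Tnf (-0.46, adjusted p = 0.0153) lower.

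Between the populations under anti-PD-1, 299 genes passed, 177 higher and 122 lower in asGM1-positive cells, and 33 and 93 of them changed at least 2-fold. DESeq2 called 853, limma voom 618 and edgeR with the pair as a block 929 (531 higher, 398 lower). Under anti-PD-1, both libraries of replicate 2 stood apart in heat shock RNA (Hspa1a at 151 and 146 CPM, against 22.5 to 32.6 CPM in the other 4 libraries). Without those 2 libraries, an alternative chosen after seeing the data, 17 genes passed, 4 higher and 13 lower. Siglech, Tcf7 and Itgae were then still past the threshold, and Ly6d, Ccr9, Foxp3, Cdk1, Birc5, Aurkb, Cdc45, C1qa, C1qb, C1qc, Apoe and Gzmk were not (edgeR adjusted p from 0.0574 to 0.365). The count moved by over 1.5 times without asGM1-negative replicate 1 (118; 50 higher, 68 lower), 2 (65; 24 and 41) or 3 (86; 38 and 48) of the anti-PD-1 groups. It also did without asGM1-positive replicate 1 (171; 107 and 64), 2 (129; 64 and 65) or 3 (82; 33 and 49). The larger share of genes higher in asGM1-positive cells was lost in 5 of these 6 cases.

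The same question was asked of both treatments together. Of the genes called under each treatment, 91 were shared, 19 higher and 72 lower in asGM1-positive cells in both and 0 in opposite directions, where independent lists of these sizes would share 0.645 and 1.14. These comparisons have no library in common. Of the 243 genes called under isotype, 219 had the same sign under anti-PD-1, and of the 299 called under anti-PD-1, 279 had the same sign under isotype. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.333 (Spearman 0.268). Over 9358 genes with an average log2 CPM of at least 3 it was r = 0.510. The count of shared genes was 251 with the pair as a block, 229 by DESeq2 and 10 without both libraries of anti-PD-1 replicate 2. It moved by over 1.5 times without isotype asGM1-negative replicate 1 (43), 2 (50) or 3 (58), anti-PD-1 asGM1-negative replicate 1 (55), 2 (35) or 3 (43) or anti-PD-1 asGM1-positive replicate 1 (54), 2 (48) or 3 (44).

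Averaged over treatments, asGM1-positive cells were lower in Siglech (-8.41 ± 0.65, edgeR adjusted p = 9.25e-05), Ly6d (-7.48 ± 0.68) and Ccr9 (-5.70 ± 0.76) and higher in C1qc (2.09 ± 0.18), C1qb (2.08 ± 0.20), Apoe (2.04 ± 0.17) and Lyz2 (1.93 ± 0.25). Tcf7 fell by 3.01 ± 0.34 and Slamf6, a marker of stem-like exhausted cells, by 1.27 ± 0.24 on the log2 scale. Entpd1 rose by 0.57 ± 0.06, Gzmk by 1.05 ± 0.17 and Gzmb by 0.62 ± 0.10. Of 33 mitosis genes 21 rose and 12 did not pass (32 rose adjusted over the list alone; camera adjusted p = 8.00e-31; adjusted p = 0.0950 with an estimated correlation, and 0.0476 with the pair as a block as well). The naive and stem-like memory list (median -0.71) and the CD4 and regulatory T cell markers (median -0.62) were lower by camera with the block and an estimated correlation (adjusted p = 0.0476 each). In all 678 genes passed, 298 higher and 380 lower, and 1662 with the block (865 higher, 797 lower). Without both libraries of anti-PD-1 replicate 2 it was 284, with Gzmk and Gzmb no longer past the threshold (edgeR adjusted p = 0.0520 and 0.0536). The count moved by over 1.5 times without isotype asGM1-negative replicate 1 (415) or anti-PD-1 asGM1-negative replicate 2 (413) or 3 (450).

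In asGM1-negative cells, the cholesterol synthesis, glycolysis and cell cycle lists were lower under anti-PD-1 than under isotype. Of 21 cholesterol synthesis genes, 16 fell and 5 did not pass (18 fell adjusted over the list alone), with a median log2 change of -0.78 (camera adjusted p = 1.53e-15; adjusted p = 0.231 with an estimated correlation), among them the enzyme genes Fdps (-2.07 ± 0.18, edgeR adjusted p = 0.000159), Idi1 (-1.90 ± 0.21) and Cyp51 (-1.95 ± 0.24). Of 33 mitosis genes, 23 fell, 1 rose and 9 did not pass (31 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.61e-18; adjusted p = 0.231 with an estimated correlation), and Cdk1 fell from 116 ± 8.22 to 62.0 ± 3.27 CPM (-0.91 ± 0.11). Of 30 DNA replication genes, 17 fell and 13 did not pass (27 fell adjusted over the list alone; camera adjusted p = 1.52e-17; adjusted p = 0.231 with an estimated correlation). Of 20 glycolysis genes, 6 fell and 14 did not pass (adjusted over the list alone, 9 fell and 1 rose; camera adjusted p = 7.09e-06; adjusted p = 0.273 with an estimated correlation), including Pgk1 (-0.60 ± 0.08) and Tpi1 (-0.63 ± 0.08).

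Of 18 effector cytokine and chemokine genes, 4 fell, 3 rose and 11 did not pass in asGM1-negative cells (5 fell and 4 rose adjusted over the list alone; camera adjusted p = 0.330). Of 15 tissue residency genes, 5 fell, 3 rose and 7 did not pass (5 fell and 3 rose adjusted over the list alone; camera adjusted p = 0.274). Ccl1 and Xcl1, chemokines secreted by activated T cells, fell from 184 ± 24.1 to 16.6 ± 3.52 CPM (-3.47 ± 0.25, edgeR adjusted p = 4.24e-05) and from 137 ± 25.1 to 13.7 ± 4.52 CPM (-3.32 ± 0.31, adjusted p = 0.000206). Zfp683, which encodes the residency factor Hobit, fell by 3.23 ± 0.29, Crybg2 by 2.47 ± 0.26 and Bcl2, which protects from apoptosis, by 2.26 ± 0.15 on the log2 scale. The largest rises were in Serpine2, a protease inhibitor (29.8 ± 3.67 to 370 ± 63.4 CPM; 3.63 ± 0.32, adjusted p = 0.000166), Serpinb9b, of the granzyme inhibitor family (45.9 ± 11.2 to 419 ± 176 CPM; 3.19 ± 0.42, adjusted p = 0.00113), Rasd2 (2.99 ± 0.41), Klrg1, a receptor of effector cells (2.48 ± 1.05 to 17.6 ± 8.24 CPM; 2.83 ± 0.54, adjusted p = 0.00853), and the metallothionein gene Mt2 (2.68 ± 0.35). Of 18 cytotoxic granule genes, 5 rose, 2 fell and 11 did not pass (6 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.274). Among them Gzme rose by 2.26 ± 0.32 and Gzmd by 1.94 ± 0.38. Gzmb was at 4597 ± 625 and 4387 ± 474 CPM and did not pass (-0.07 ± 0.15, adjusted p = 0.842).

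Inhibitory receptor genes were higher as a list under anti-PD-1 in asGM1-negative cells. Of 23 inhibitory receptor and exhaustion genes, 9 rose, 2 fell and 12 did not pass (12 rose and 2 fell adjusted over the list alone; camera adjusted p = 2.09e-06; adjusted p = 0.231 with an estimated correlation). Havcr2, which encodes TIM-3, rose from 440 ± 51.6 to 948 ± 143 CPM (1.11 ± 0.12, edgeR adjusted p = 0.000487), Rgs16 by 0.99 ± 0.09 and Pdcd1 from 1487 ± 199 to 2300 ± 117 CPM (0.63 ± 0.11, adjusted p = 0.00411). Cd244a was one of the 2 that fell (-0.91 ± 0.13). Of 24 naive and stem-like memory genes, 3 rose, 5 fell and 16 did not pass (7 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.626), with Satb1 (1.19 ± 0.11) and Lef1 (1.72 ± 0.18), transcription factors of early T cells, among the risers. Of 19 fatty acid oxidation genes, Cpt1a (1.54 ± 0.18) and Slc25a20 (1.02 ± 0.09), which carry fatty acids into mitochondria, were among 3 that rose, 1 fell and 15 did not pass (7 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.0327, higher; adjusted p = 0.400 with an estimated correlation). The list call ended with library size alone (0.0702) and without isotype asGM1-negative replicate 1 or 2 or anti-PD-1 asGM1-negative replicate 2 (0.0561, 0.0572 and 0.0821).

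The treatment contrast in asGM1-negative cells called 1633 genes, 785 higher and 848 lower under anti-PD-1 (48.1% higher), of which 222 and 234 changed at least 2-fold. Scaled by library size alone, 666 were higher and 1117 lower (37.4% higher). DESeq2 called 2756 and limma voom 2779, and 813 genes passed without both libraries of anti-PD-1 replicate 2. The count moved by over 1.5 times without isotype asGM1-negative replicate 1 (862) or anti-PD-1 asGM1-negative replicate 1 (818), 2 (1000) or 3 (778). All genes named here for this contrast as risen or fallen passed with each library left out. Heat shock RNA was also lower under anti-PD-1, in which the named cholesterol and glycolysis genes fell: Hsp90aa1 fell from 370 ± 6.15 to 214 ± 27.1 CPM (-0.79 ± 0.10, edgeR adjusted p = 0.000913), and of 10 heat shock genes, listed after the data were seen, 3 fell and 7 did not pass (8 fell adjusted over the list alone).

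In asGM1-positive cells, the cholesterol synthesis and glycolysis lists were also lower under anti-PD-1 than under isotype. Of 21 cholesterol synthesis genes, 17 fell and 4 did not pass (19 fell adjusted over the list alone; median -0.87; camera adjusted p = 2.55e-21; adjusted p = 0.157 with an estimated correlation), among them Fdps (-2.35 ± 0.18, edgeR adjusted p = 3.31e-05) and Sqle (-1.68 ± 0.19). Of 20 glycolysis genes, 9 fell, 1 rose and 10 did not pass (10 fell and 2 rose adjusted over the list alone; camera adjusted p = 1.78e-06; adjusted p = 0.286 with an estimated correlation). Among residency genes, Zfp683 fell from 51.2 ± 8.64 to 2.44 ± 0.803 CPM (-4.39 ± 0.31, adjusted p = 1.95e-05) and Itgae from 37.6 ± 6.96 to 2.40 ± 0.588 CPM (-3.97 ± 0.29, adjusted p = 2.53e-05). Of 15 tissue residency genes, 6 fell, 1 rose and 8 did not pass (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 8.39e-05; adjusted p = 0.296 with an estimated correlation). Xcl1 fell by 3.97 ± 0.32, Ccl1 by 3.34 ± 0.25 and Bcl2 by 2.18 ± 0.15 on the log2 scale.

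The largest rises in asGM1-positive cells were in Ceacam1, an adhesion and inhibitory receptor (0.963 ± 0.815 to 27.1 ± 3.33 CPM; 4.83 ± 0.56, edgeR adjusted p = 0.000393), Serpinb9b (4.08 ± 0.44), Serpine2 (26.7 ± 11.6 to 431 ± 99.5 CPM; 4.02 ± 0.33, adjusted p = 4.17e-05), Tg, the thyroglobulin gene (3.65 ± 0.32), Mirt1 (2.91 ± 0.39) and Itgb3, an integrin subunit (2.77 ± 0.18). Lef1 rose by 2.55 ± 0.19, Satb1 by 1.67 ± 0.11 and Il7r by 1.05 ± 0.13. Of 24 naive and stem-like memory genes, 9 rose, 6 fell and 9 did not pass (11 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.0702). Of 23 inhibitory receptor and exhaustion genes, 8 rose, 2 fell and 13 did not pass (12 rose and 2 fell adjusted over the list alone; camera adjusted p = 1.78e-06; adjusted p = 0.202 with an estimated correlation), with Rgs16 at 1.02 ± 0.09 and Havcr2 at 0.89 ± 0.12. Among 18 cytotoxic granule genes 3 rose, 3 fell and 12 did not pass (4 rose and 6 fell adjusted over the list alone), with Gzmc falling from 2573 ± 601 to 510 ± 183 CPM (-2.34 ± 0.33, adjusted p = 0.00147) and Serpinb9, the granzyme B inhibitor, rising by 1.74 ± 0.19. Of 33 mitosis genes, only Cenpa, a centromeric histone, passed, and it rose (0.76 ± 0.09; 1 rose adjusted over the list alone), while the list as a whole was lower by camera (median -0.17, adjusted p = 0.00541; adjusted p = 0.585 with an estimated correlation), a call lost without isotype asGM1-positive replicate 3 (camera adjusted p = 0.423).

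The treatment contrast in asGM1-positive cells called 1274 genes, 706 higher and 568 lower, of which 327 and 282 changed at least 2-fold. DESeq2 called 2264, edgeR on the 6 libraries compared 694, and edgeR without both libraries of anti-PD-1 replicate 2 616. The count moved by over 1.5 times without anti-PD-1 asGM1-positive replicate 1 (683) or 2 (692). Fn1, a matrix gene of fibroblasts, fell from 26.4 ± 20.9 to 1.93 ± 0.790 CPM (-3.77 ± 0.66, edgeR adjusted p = 0.00568). Isotype asGM1-positive replicate 1 stood highest in it (50.4 CPM, against 12.2 and 16.5), and without that library the change was -2.89 (adjusted p = 0.0154). Of 13 fibroblast and endothelial markers, 2 fell, 1 rose and 10 did not pass (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.103). Of 10 heat shock genes, listed after the data were seen, 4 fell and 6 did not pass (9 fell adjusted over the list alone).

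**Figure D3:**
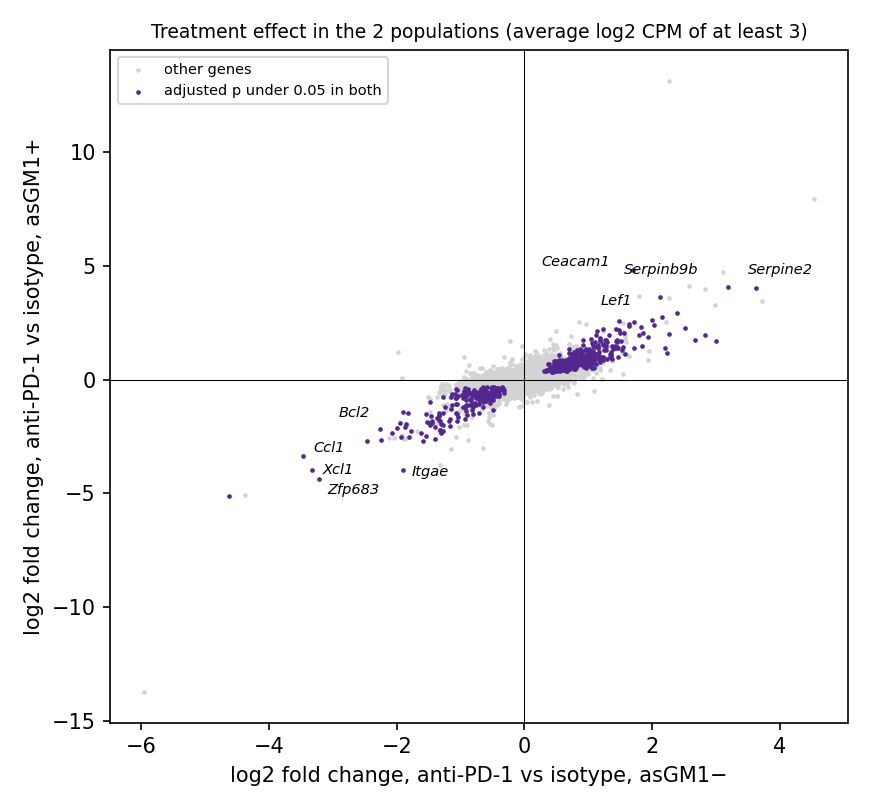
Log2 fold change of anti-PD-1 over isotype in asGM1-negative cells (x) and asGM1-positive cells (y), 1 point per gene with an average log2 CPM of at least 3. Genes with an edgeR adjusted p under 0.05 in both are drawn dark and lie mostly along the diagonal, as for Ccl1 at -3.47 and -3.34 and Serpine2 at 3.63 and 4.02.

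The treatment effects of both populations were set side by side. They shared 683 calls, 404 higher and 279 lower, where independent lists would share 29.7 and 25.8, and 2 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.389 (Spearman 0.493). Over 9358 genes with an average log2 CPM of at least 3 it was r = 0.755. The contrasts share no library, but both populations of a pair enter them, so part of this overlap may come from the pairs. Averaged over populations, 3417 genes passed, 1720 higher and 1697 lower, among them Zfp683 (-3.81 ± 0.21, edgeR adjusted p = 1.08e-06), Xcl1 (-3.65 ± 0.22) and Ccl1 (-3.41 ± 0.18), which fell, and Serpine2 (3.83 ± 0.23) and Serpinb9b (3.64 ± 0.30), which rose. Il7r rose by 0.92 ± 0.09, Gzmk by 1.17 ± 0.17, Pdcd1 by 0.47 ± 0.07 and Klrg1 by 2.39 ± 0.38. Of 21 cholesterol synthesis genes 18 fell and 3 did not pass (20 fell adjusted over the list alone; camera adjusted p = 1.93e-18; adjusted p = 0.223 with an estimated correlation). Libraries of a pair are not independent in this contrast, so its standard errors and p-values may be too small. With the counts of both populations of a pair summed, an alternative chosen after seeing the data, 1299 genes passed. Of the 109 named calls of this contrast compared, 78 were kept with summed pairs. Without anti-PD-1 replicate 2, 2148 genes passed.

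**Figure D4:**
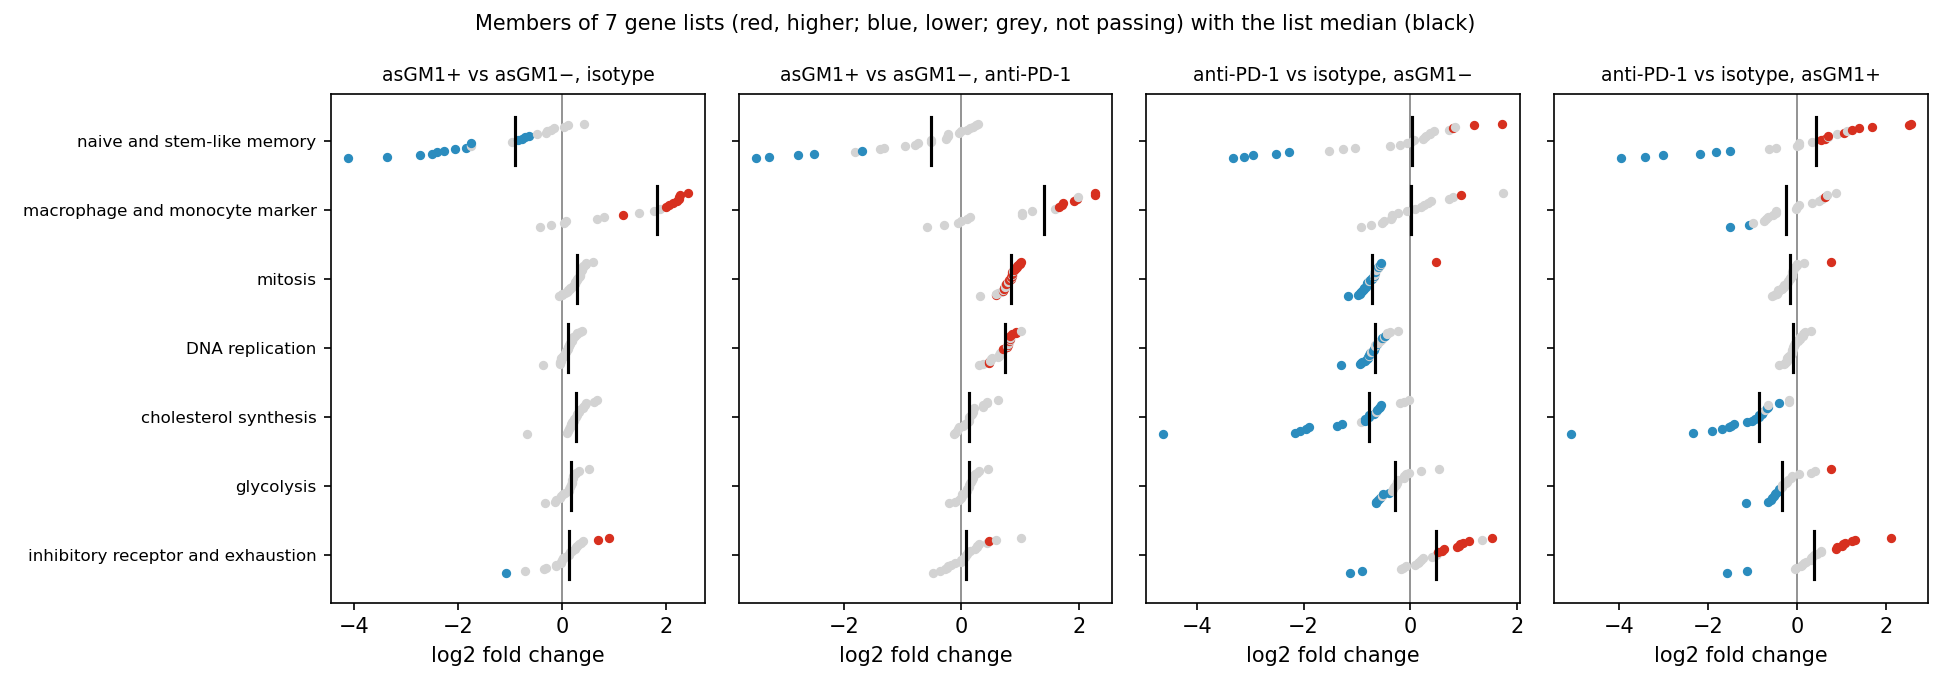
Log2 fold changes (x) of the members of 7 gene lists (y; points, red or blue where the gene passed over all genes tested) for the population contrasts and the treatment contrasts, with the median of each list as a bar. Mitosis genes have medians of 0.29 under isotype and 0.84 under anti-PD-1 between populations, and cholesterol synthesis genes of -0.78 and -0.87 between treatments.

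Whether the response to anti-PD-1 differed between the populations was tested as the interaction. No gene passed with edgeR (0 of 18657, smallest adjusted p = 0.269), while 1341 genes had an unadjusted p under 0.05, against 933 expected by chance. DESeq2 called 136 genes, 68 in each direction, limma voom 0, and edgeR with the pair as a block 13. The 13 were Tnfrsf4, Cd160, Top2a, Pclaf, Lig1 and Zdhhc14, more positive in asGM1-positive cells, and Aldoc, Ifit3, Ifit3b, Cd274, Slc26a11, Zfp683 and Anxa1, more negative, names chosen after their values were seen. Of the gene lists, DNA replication (median 0.62, camera adjusted p = 2.04e-19; adjusted p = 0.377 with an estimated correlation) and mitosis (camera adjusted p = 7.51e-19; adjusted p = 0.384 with an estimated correlation) were more positive in asGM1-positive cells, with 0 members passing over all genes and 12 and 8 adjusted over the list alone. Tissue residency genes were more negative (median -0.61, camera adjusted p = 2.13e-09; adjusted p = 0.377 with an estimated correlation), with 0 members passing over all genes and 7 lower adjusted over the list alone.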

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

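The tests weighed in this part were chosen after the results they bear on had been seen.

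For 11 gene lists the effect of anti-PD-1 differed between the populations by camera's test of the interaction, and for none of them did that hold with an estimated correlation. Cell cycle genes stood first: DNA replication (adjusted p = 2.04e-19; adjusted p = 0.377 with an estimated correlation) and mitosis (7.51e-19; 0.384) fell in asGM1-negative cells under anti-PD-1 by medians of -0.67 and -0.72, against -0.10 and -0.17 in asGM1-positive cells. Tissue residency genes were more negative in asGM1-positive cells (2.13e-09; 0.377), as were interferon response genes (6.92e-06; 0.667; median -0.42). Mitochondrially encoded genes (5.07e-08; 0.483; median 0.51) and naive and stem-like memory genes (0.000193; 0.483; median 0.41) were more positive. Ribosomal protein genes were more positive (0.000734; 0.823), a call lost without isotype asGM1-negative replicate 1 (0.317), isotype asGM1-positive replicate 3 (0.397) or anti-PD-1 asGM1-positive replicate 3 (0.610). CD8 T cell markers (0.00129; 0.483), cytotoxic granule genes (0.00617; 0.598), NK receptor genes (0.0229; 0.483) and glycosphingolipid genes (0.0229; 0.598) were more negative. Without anti-PD-1 asGM1-positive replicate 1 these 4 calls ended (0.0777, 0.0777, 0.673 and 0.130). The cytotoxic list was also lost without isotype asGM1-negative replicate 3 (0.0547), isotype asGM1-positive replicate 2 (0.0696) or anti-PD-1 asGM1-negative replicate 2 (0.100). The NK receptor list was lost without isotype asGM1-negative replicates 2 or 3 (0.102 and 0.130), isotype asGM1-positive replicates 1 or 3 (0.217 and 0.0926) or anti-PD-1 asGM1-negative replicates 2 or 3 (0.118 and 0.0953). The glycosphingolipid list was lost without isotype asGM1-negative replicate 2 (0.0808), isotype asGM1-positive replicate 3 (0.171), anti-PD-1 asGM1-negative replicates 2 or 3 (0.0634 and 0.0505) or anti-PD-1 asGM1-positive replicate 3 (0.201), and with library size alone (0.0609).

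Under anti-PD-1, mitosis and DNA replication genes were higher in asGM1-positive than in asGM1-negative cells. Non-T cells without cycling, mixed into the asGM1-negative libraries, would lower the CD8 T cell markers there too. Those differed by a median of -0.0982 (quartiles -0.19 to -0.03), in the other direction and below the 0.42 (0.5 times the mitosis median) that such dilution would need. Resting T cells would not lower that list, which holds general T cell genes such as Cd3e and Trac. Naive and CD4 and regulatory T cell genes were higher in those asGM1-negative libraries, so dilution by resting T cells stays open. A single tumour did not carry the pattern either: in the same-numbered pairs the median difference of the 63 genes was 0.71 (0.707), 0.86 and 0.80, with 63 of 63 genes higher each time, against 0.28, 0.20 and 0.18 under isotype. A difference in proliferation between the populations stays open as a hypothesis that was not tested further.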

How the results depend on the processing

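Alternatives without both libraries of anti-PD-1 replicate 2, with summed pairs, or with the block and an estimated correlation together were chosen after seeing the data. Of 418 calls of named genes, DESeq2 kept 418, RLE size factors 416, library size alone 411, limma voom 400, no filter 396, the number shared by all groups as a block 396, and a left-out library 340 to 386; 299 were kept without anti-PD-1 replicate 2, 205 of 251 with only the groups compared, 78 of 109 with summed pairs and 126 of 131 with the pair as a block. No named gene reversed. DESeq2 called 798 and 853 genes for the population effect under isotype and anti-PD-1, 2756 and 2264 for treatment in asGM1-negative and asGM1-positive cells, 1419 for the averaged population effect, 136 for the interaction and 229 shared calls; its simulated share of false calls was 16.3%. Limma voom called 618 under anti-PD-1 and 2779 for treatment in asGM1-negative cells. Only the 2 groups compared gave 80 (isotype) and 694 (treatment, asGM1-positive), where fewer libraries entered the fit. The replicate block within treatment gave 755, 929, 1662, 13 and 251 for the population effects under isotype, under anti-PD-1 and averaged, the interaction and shared calls. Without anti-PD-1 replicate 2, with fewer samples, counts were 17 (population, anti-PD-1), 813 and 616 (treatment), 284 and 2148 (averaged population and treatment) and 10 (shared); summed pairs gave 1299.

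Leaving out 1 library gave 86 to 230 genes for the population effect under isotype, 65 to 379 under anti-PD-1, 778 to 1782 and 683 to 1276 for treatment in asGM1-negative and asGM1-positive cells, 413 to 823 for the averaged population effect and 35 to 80 shared calls. Of 101 list calls, fry made 50 calls of its own and kept 44, and an estimated correlation kept 2; among population effects and the interaction (66 calls) fry made 22, an estimated correlation 2 and that with the block 10. The interferon response list under isotype (adjusted p = 0.881) reversed and passed without isotype asGM1-negative replicate 3 or asGM1-positive replicate 1, at 0.0199 and 0.00977, and passed in the main direction without asGM1-negative replicate 1 (0.000643) or asGM1-positive replicate 3 (0.0269) (other values signed by direction ran, over left-out libraries, from -0.844 to 0.860). For all of these except where fewer samples are named, the cause was not tested. With the pair as a block the inhibitory receptor list under isotype (0.0847), the gamma-delta list under isotype and anti-PD-1 (0.0979 and 0.186) and Ccl22 (0.0671) and Clec9a (0.0507) under anti-PD-1 were no longer called, nor were the inhibitory receptor (0.0627), gamma-delta (0.0880) and NK receptor (0.141) lists averaged over treatments. Lists newly called with it were fibroblast and endothelial (0.0101) and erythroid and platelet markers (0.0238) under isotype and NK cell (0.00178) and erythroid and platelet markers (0.0407) averaged, all higher; stress genes (0.0174) and CD8 T cell markers (0.0181) under anti-PD-1, both lower; and oxidative phosphorylation (0.0295, positive) and stress genes (0.00250, negative) in the interaction. None of these new calls held with an estimated correlation as well (adjusted p from 0.181 to 0.690). Filters and scalings moved no count of genes by over 1.5 times. At 58.1 to 73.2 M counts per library, depth limits genes under 0.0516 CPM.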

Other observations

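The comparison of V segment use and all tests of explanations in this part were chosen after the results were seen, except the test with the heat shock level as a covariate. The heat shock list behind that covariate was itself added after the data were seen.

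T cell receptor V segments were used less evenly by asGM1-positive cells. The effective number of Trav segments is the exponential of the entropy of their counts, so it is lower when few segments dominate. It was 40.8 ± 8.66 in asGM1-negative and 27.0 ± 7.16 in asGM1-positive libraries (SD over both treatments, n = 6 each). In 6 of 6 same-numbered pairs it was lower in asGM1-positive cells, with a mean difference of -13.8 ± 4.39. For Trbv segments it was 11.5 ± 0.689 and 8.92 ± 0.671, again lower in 6 of 6 pairs, by a mean of -2.55 ± 1.05. An exact two-sided sign-flip test gave p = 0.0313 for each, which is the smallest that 6 pairs can give, and 0.0313 after adjustment over both tests. Use of reads that match several segments was not stated, so the shares of near-identical duplicated Trav segments are uncertain. CD4 and regulatory T cell markers were lower in the same asGM1-positive libraries (mean log2 CPM of the list 5.20 ± 0.195 in asGM1-negative and 4.22 ± 0.149 in asGM1-positive cells under isotype, 5.22 ± 0.208 and 4.34 ± 0.140 under anti-PD-1). The CD8+ sort would remove CD4+ cells. Any that remained in the asGM1-negative libraries would add V segments there, and no test separated their segments from those of CD8+ cells.

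Naive and stem-like memory genes were lower in asGM1-positive cells. A candidate source is plasmacytoid dendritic cells in the asGM1-negative libraries, since the gate named no T cell receptor marker and Siglech reached 58.6 CPM there. CD4 and regulatory T cells were weighed too because Foxp3 reached 29.0 CPM there, although the CD8+ gate would remove CD4+ cells and goes against that source. If 1 admixed type brought all these genes, their differences in CPM would shrink by the same factor from isotype to anti-PD-1. The median log2 ratio was -0.57 for 14 naive genes and -0.98 for 14 plasmacytoid genes (-2.04 to -0.68), a gap of 0.402 (permutation p = 0.0118). For the list as a whole the gap stayed under the 0.5 set for excluding that source. Yet 8 of the 14 naive genes lay above every plasmacytoid gene, while Dapl1 (-3.36) and Id3 (-2.40) lay below every one. The difference of Tcf7, 1 of these 8, went from 59.4 to 65.5 CPM, while that of Siglech shrank from 58.5 to 30.3 CPM. These 8 genes were picked by the same ratios. The ratios measure admixture only where treatment leaves a gene unchanged within each cell type. Satb1, another of the 8, rose in asGM1-positive libraries, from 64.3, 67.6 and 78.9 CPM to 223, 240 and 210 CPM. Siglech was at most 0.489 CPM in those libraries. For these 8 genes the ratios therefore cannot decide whether plasmacytoid cells were the only source. Against 4 CD4 and regulatory T cell genes the gap was -0.55 (permutation p = 0.377), with too few genes to decide. Of these 4, Tnfrsf4 (log2 ratio -1.83) is also in the T cell receptor activation list and so is not specific to that source. Plasmacytoid cells, CD4 and regulatory T cells and a true difference between CD8+ populations cannot be told apart here.

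Cholesterol synthesis genes were lower under anti-PD-1. Macrophages or fibroblasts in the isotype libraries do not account for it as a whole, because under isotype the list differed between populations by a median of 0.264 (quartiles 0.17 to 0.39) where the macrophage markers differed by 1.82 and the fibroblast and endothelial markers by 2.43 (0 of 13 passed). The CD45.2+ gate would also remove fibroblasts. Col1a1, an abundant transcript of theirs named after its values were seen, was at 0.277 CPM in isotype asGM1-negative cells, where Fdps fell from 84.6 to 20.2 CPM. That value covers asGM1-negative cells only. In isotype asGM1-positive replicates 1, 2 and 3 the fibroblast gene Fn1 was at 50.4, 12.2 and 16.5 CPM. Handling stress could contribute: heat shock RNA was also lower, and with the heat shock level of each library as a covariate the list's median moved from -0.85 to -0.566 (quartiles -1.14 to -0.46) and the members called from 18 to 3. That covariate nearly follows the treatment, and the genes called went from 3417 to 138, so the lost calls do not show that stress was the cause. A batch between treatments was not given in the labels, so an effect of PD-1 inhibition, stress and batch cannot be told apart.

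Other splits of the samples were fitted in the same way. For the population effect averaged over treatments, exchanging populations within pairs gave 32 splits, of which 1, the real one, called as many genes (678, highest other 1). A share of 1 in 32 is the smallest that these splits can give. It lies under 0.05 and makes chance less likely there without excluding it. The simple contrasts have 10 splits each, too few for a share under 0.05. Their real counts and highest others were 243 and 2 for the population effect under isotype, 299 and 1 under anti-PD-1, 1633 and 0 for treatment in asGM1-negative cells and 1274 and 0 in asGM1-positive cells. For the averaged treatment effect, whole pairs were exchanged, and the 10 splits gave 3417 and 6. In each of these 1 of 10 splits, the real one, called as many genes. Of the 10 splits of each simple population contrast, 6 part only 1 of the 3 pairs and leave the others whole on 1 side. Among the 4 that part all 3, the highest others were 0 under isotype and 1 under anti-PD-1. For the interaction all 10 splits called 0 genes.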
